A study of Homo sapiens with 8 samples.

How the data were processed

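The values analysed are the deposited counts, per the labels from 8 strand-specific, rRNA-depleted, paired-end RNA-seq libraries of Caco-2/15 cells sequenced on an Illumina NextSeq instrument. The authors' processing notes name STAR 2.5.2b, SAMtools, HTSeq and hg38. The gene annotation used for counting, the HTSeq mode and its strand setting are not given in the sources used here. The deposited tables hold raw counts for 58302 Ensembl gene IDs and the HTSeq classes of unassigned reads. Of these IDs, 58039 are in GENCODE v29, which gave positions on GRCh38, and 57532 have a symbol in the gene name table. All mitochondrial gene IDs stand at 0 in every library, so mitochondrial transcripts were not analysed here.

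Depth was 17063826 to 40881682 gene counts per library. Reads overlapping no feature made up 20.6% to 32.0% of all reads listed, with the highest shares in subconfluent and postconfluent Z1flag replicate 1. Ambiguous reads made up 5.39% to 7.86% and reads aligned to more than 1 place 6.59% to 10.3%. Counting intervals cover counting error only.

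Groups were taken from the labels: Z1flag or Z2flag, subconfluent or postconfluent, with 2 libraries each. Replicates carry experiment numbers. Whether these are separate cultures, or mark the same experiment in both lines, is not given in the sources used here. The tests therefore measure the spread between these samples. Across genes, deviations of libraries with the same number correlated weakly over the pairs of groups, with r from -0.18 between the postconfluent groups to 0.178 between subconfluent Z1flag and postconfluent Z2flag cells, and no replicate block was used in the chosen fit. A replicate block was an alternative.

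Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood fit, F test) in 1 fit of 4 group means with 4 residual degrees of freedom. The edgeR filterByExpr filter (minimum count 10, minimum total 15, by group) left 18240 genes. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 7 contrasts were the mean confluence change over both lines, the change in each line, the difference between these changes (interaction), and the difference between lines over both states and within each state. The change within Z1flag and within Z2flag cells used different libraries. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. The SE of an edgeR log2 fold change is its size divided by the square root of the F statistic. It therefore follows from the test and can understate counting error where counts are few.

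The 30 gene lists, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The lists cover enterocyte functions, other intestinal and non-intestinal cell types, proliferation, chromatin, metabolism and stress. The histone symbols H2AC18, H3C2 and H3C3 had no match. Lists with at least 5 tested genes were tested by camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and by fry. Named were H2AZ1 and H2AZ2, the 8 higher and 8 lower genes with the largest change among those that passed with mean CPM of at least 5 and no overlap between states, the 3 interaction genes with the smallest p, since none passed, and up to 3 members of each list with the smallest adjusted p and mean CPM of at least 1, with the first of the other direction. Differences between lines had no gene to name by this rule. Shares of read classes were compared by two-sided exact permutation tests over the 8 libraries, for which the smallest possible p is 0.0286.

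The pipeline was tested on simulated counts with 200 changed genes per contrast. For the confluence contrast it recovered 53.1% of genes changed 2-fold and 89.7% of genes changed 4-fold with 5 false calls, within Z1flag cells 19.2% and 72.4% with 9, within Z2flag cells 17% and 79.6% with 12, and for lines over both states 52% and 95.9% with 15. For lines it recovered 18.2% and 74% with 20 false calls in subconfluent cells, and 13% and 68% with 5 in postconfluent cells. In the data far more genes were called: 55.4% for confluence, 40.5% within Z1flag and 37.6% within Z2flag cells. The Benjamini-Hochberg cut-off depends on that share, so the simulated recovery does not carry over to these 3 contrasts.

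Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom, no filter, a filter of CPM of at least 5 in 2 libraries, a fold change of at least 2, replicate blocks, fits of state or line alone, fits of only the libraries compared, removal of small structural RNA, and leaving out each library. Added after the data were seen were a fit without the 2 libraries of highest no-feature share, that share as a covariate, a crossed replicate block for postconfluent cells, and 9 gene families defined by symbol. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.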

Results

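RNA-seq was carried out on Caco-2/15 cells, a human colon cancer cell line that takes on features of absorptive enterocytes once its cultures are confluent. The 2 genome-edited populations compared each carry a Flag epitope tag on 1 copy of a gene for the histone variant H2A.Z. Z1flag cells have the tag on H2AFZ (now H2AZ1, protein H2A.Z.1) and Z2flag cells on H2AFV (now H2AZ2, protein H2A.Z.2). Each population was sampled subconfluent and 7 days after confluence, with 2 libraries in each of the 4 groups. Counts assigned to genes ranged from 17063826 in postconfluent Z2flag replicate 2 to 40881682 in subconfluent Z2flag replicate 1. Per the labels, the series asks how each H2A.Z isoform contributes to the change of expression during enterocyte-like differentiation. The libraries of the 2 states separated along the first principal component, which held 71.7% of the variance. The second, with 13.1%, set postconfluent Z1flag replicate 1 (73.9) at the opposite end from postconfluent Z2flag replicate 1 (-55.7).

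Both H2A.Z genes were lower after confluence. H2AZ1 fell from 333 ± 27.8 to 171 ± 42.2 CPM (SD, n = 4 libraries per state), a log2 fold change of -0.97 (SE 0.19, edgeR adjusted p = 0.0016), and H2AZ2 fell from 92.1 ± 5.17 to 53.3 ± 7.11 CPM, a log2 fold change of -0.79 (SE 0.14, adjusted p = 0.000911). H2AZ1 lies on chromosome 4 at 99948086 to 99950388 and H2AZ2 on chromosome 7 at 44826791 to 44848083, both on the minus strand of GRCh38, and counts per gene do not separate the tagged from the untagged allele. The fall was found in each tagged line: H2AZ1 changed by -1.05 (SE 0.27, adjusted p = 0.0108) in Z1flag and -0.89 (SE 0.26, adjusted p = 0.0246) in Z2flag cells, and H2AZ2 by -0.87 (SE 0.20, adjusted p = 0.00664) and -0.72 (SE 0.20, adjusted p = 0.0173). Postconfluent Z1flag replicate 1 had the lowest level of both genes, 108 CPM for H2AZ1 and 42.8 CPM for H2AZ2, against 187 to 197 CPM and 55.3 to 58.2 CPM in the other postconfluent libraries.

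A list of 32 genes holds both H2A.Z genes with exchange proteins and readers of the variant, and 15 of them, H2AZ1 and H2AZ2 included, fell after confluence while 1 rose (median log2 fold change -0.37, or -0.18 with upper-quartile scaling, which raised the median of all genes). The median member lay at -0.65 relative to the subconfluent mean in postconfluent Z1flag replicate 1 and at -0.24 to -0.38 in the other postconfluent libraries. RUVBL1, an ATPase shared by the exchange complexes, fell from 105 ± 7.52 to 25.6 ± 5.39 CPM (SD, n = 4; log2 fold change -2.05, SE 0.16). EPC2, a subunit of the NuA4 acetyltransferase complex, and ANP32E, a chaperone that removes H2A.Z, fell by 1.46 (SE 0.14) and 1.24 (SE 0.15) on the log2 scale. PWWP2B, which binds H2A.Z chromatin, was the 1 member that rose (log2 fold change 1.48, SE 0.23), and 2 members rose without postconfluent Z1flag replicate 1 or postconfluent Z2flag replicate 2. The list as a whole passed the camera test (adjusted p = 0.00848) but not with an estimated correlation, where adjusted p = 0.478 with an estimated correlation.

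**Figure D1:**
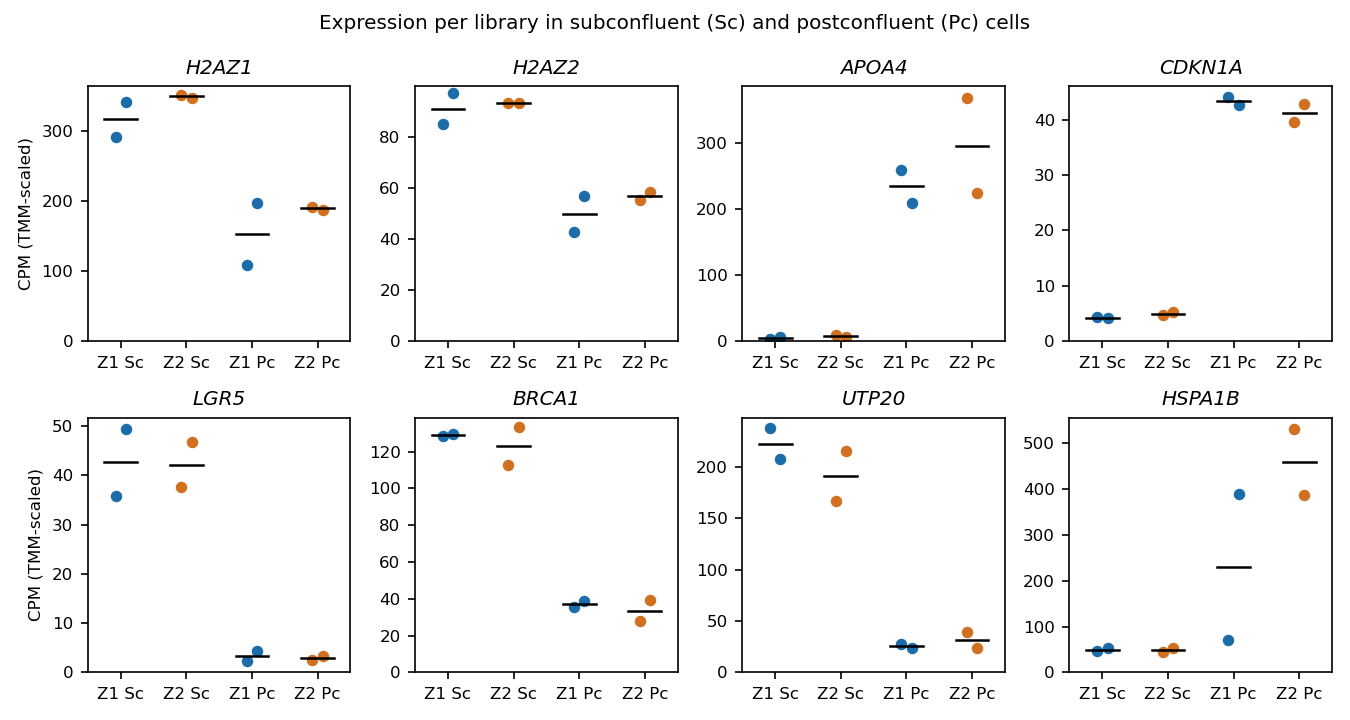
Expression of 8 genes in CPM (y axes start at 0) in each library, with Z1flag libraries in blue, Z2flag libraries in orange and a black bar at the mean of the 2 libraries of a group. H2AZ1, H2AZ2, LGR5, BRCA1 and UTP20 were lower and APOA4, CDKN1A and HSPA1B higher in all 4 postconfluent (Pc) than in all 4 subconfluent (Sc) libraries, and HSPA1B reached 69.9 CPM in postconfluent Z1flag replicate 1 against 387 to 532 CPM in the other postconfluent libraries.

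The passage from subconfluent to postconfluent culture changed the expression of 10097 of 18240 genes tested, 5076 higher and 5021 lower. By at least 2-fold, 3454 were higher and 2394 lower. The largest increases included SLC51A, a subunit of the basolateral bile acid transporter, from 0.119 ± 0.0678 to 13.3 ± 1.80 CPM (SD, n = 4), and MYO7B, a myosin of the brush border, from 0.496 ± 0.321 to 33.4 ± 19.5 CPM. The largest decreases included LGR5, a receptor that marks intestinal stem cells, from 42.4 ± 6.67 to 3.11 ± 0.997 CPM, and TAGLN, an actin-binding protein of contractile cells, from 1060 ± 392 to 67.9 ± 68.8 CPM. In log2 terms SLC51A changed by 6.73 (SE 0.35), MYO7B by 6.21 (SE 0.50), LGR5 by -3.78 (SE 0.25) and TAGLN by -4.05 (SE 0.56), with edgeR adjusted p of 2.33e-06, 1.32e-05, 5.95e-06 and 0.000228.

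The other 6 named genes with the largest increases were LGI4, HSPA6, GNRH2, FXYD3, PNCK and CEACAM5. LGI4 rose from 0.0308 ± 0.0448 to 31.7 ± 1.25 CPM (SD, n = 4) and its neighbour FXYD3, a regulator of the sodium pump, from 0.152 ± 0.076 to 35.6 ± 11.7 CPM. They lie on opposite strands of chromosome 19, at 35124513 to 35142451 and 35115879 to 35124324, 189 bp apart. PNCK, a calmodulin-dependent kinase gene, rose by 7.49 (SE 0.35) and lies across part of SLC6A8, which rose by 3.95 (SE 0.22). HSPA6, a heat-inducible chaperone of the HSP70 family, had 2 counts in the 4 subconfluent and 1563 in the 4 postconfluent libraries, a depth-scaled ratio of 1202 (95% exact binomial interval 332 to 9935, for counting error only). It reached 0.908 CPM in postconfluent Z1flag replicate 1 and 25.3 to 30.9 CPM in the other 3, and it did not pass without a filter on low counts (adjusted p = 0.0611). LGI4 and GNRH2, the gene of a gonadotropin-releasing hormone, changed by 10.76 (SE 0.35) and 8.32 (SE 0.62). Their depth-scaled count ratios were 786 (95% exact binomial interval 336 to 2422) and 344 (187 to 719), again for counting error only. For LGI4 this interval is wider than an SE of 0.35 would give. CEACAM5, the carcinoembryonic antigen, changed by 6.78 (SE 0.89) with 14.3 ± 21.2 CPM after confluence. LGI4, PNCK, GNRH2 and CEACAM5 had 5, 8, 10 and 10 subconfluent counts, so their fitted log2 fold changes depend on the small prior count of the edgeR fit.

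Among the genes with the largest decreases, MYL7, a myosin light chain, fell by 4.96 (SE 0.34) on the log2 scale. SCN9A, a voltage-gated sodium channel, fell by 4.79 (SE 0.38), MYBPH, a myosin-binding protein, by 4.59 (SE 0.27) and NDST4, a heparan sulfate sulfotransferase, by 4.21 (SE 0.23). LRRN4, a leucine-rich repeat protein, fell from 73.9 ± 1.99 to 5.02 ± 1.33 CPM (SD, n = 4) and OLR1, a receptor for oxidized lipoprotein, from 200 ± 86.6 to 15.6 ± 14.2 CPM. OLR1, SLC51A, LGR5 and TAGLN each overlap another expressed gene on the opposite strand (TMEM52B, PCYT1A, TSPAN8 and PCSK7), so their counts are uncertain to the extent that the counting ignored strand. The same limit applies to other genes named here, among them PNCK, CDHR2, SLC1A1, NR1I3, CLDN2, RUVBL1, HIRA, SLC16A3, NDUFB3, ATP5PB, DDIT3, DNAJB9, CRELD2, IFIT2, JUNB and FOSB, each overlapping a protein-coding gene of the other strand. EGLN3, HLA-B and HIRA overlap an expressed protein-coding gene of the same strand (SPTSSA, HLA-C and C22orf39). Their counts can be uncertain whatever the strand setting. Upper-quartile scaling, which moved the median log2 fold change of all genes to 0.18 from -0.01 with TMM, gave 6248 higher and 3822 lower genes, 62% higher against 50.3%.

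Of 17 digestive hydrolases tested, 12 rose and 4 fell. The intestinal alkaline phosphatase ALPI went from 9.09 ± 2.88 to 53.6 ± 11.7 CPM (SD, n = 4), the aminopeptidase ANPEP from 1.34 ± 0.697 to 27.7 ± 15.5 CPM and the metalloprotease MEP1A from 0.875 ± 0.498 to 19.8 ± 4.27 CPM, while ENPEP fell by 2.05 (SE 0.32) on the log2 scale. Of 28 genes of lipid absorption and lipoproteins, 23 rose and 0 fell by edgeR's test, and 1 fell without postconfluent Z1flag replicate 1, subconfluent Z1flag replicate 1 or postconfluent Z2flag replicate 2. APOA4, an apolipoprotein of chylomicrons, went from 5.84 ± 2.14 to 265 ± 71.7 CPM, and the lipid droplet protein CIDEC and the lipase inhibitor ANGPTL4 changed by 2.68 (SE 0.17) and 4.26 (SE 0.32). Of 23 genes of brush border structure, 15 rose, among them EPS8L3, BAIAP2L2 and the protocadherin CDHR2 (log2 fold changes 2.24, 2.21 and 5.45), and 1, the myosin MYO1D, fell by 1.26 (SE 0.13).

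Of 30 nutrient and ion transporters, 14 rose and 5 fell. The peptide transporter SLC15A1 went from 7.50 ± 1.40 to 31.9 ± 6.23 CPM (SD, n = 4), the anion exchanger SLC26A6 from 30.3 ± 5.24 to 121 ± 19.7 CPM, and the glutamate transporter SLC1A1 fell by 1.57 (SE 0.19) on the log2 scale. Leaving out postconfluent Z1flag replicate 2 gave 8 transporters that fell. Of 31 genes of xenobiotic metabolism, 20 rose and 2 fell, with the ketosteroid reductase AKR1C1 at 9.14 ± 1.11 and 153 ± 88.1 CPM, the epoxide hydrolase EPHX2 at 33.3 ± 9.59 and 134 ± 40.8 CPM, and the acetyltransferase NAT1 at 13.9 ± 2.24 and 5.13 ± 1.43 CPM before and after confluence. Without postconfluent Z2flag replicate 1, 1 gene of this list fell. The median member lay at 2.03 above the subconfluent mean on the log2 scale in postconfluent Z1flag replicate 1 and at 1.10 to 1.26 in the other postconfluent libraries.

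Of 28 intestinal transcription factors, 14 rose and 6 fell, and 15 rose when adjusted over the list alone. The median member lay at 0.17 in postconfluent Z2flag replicate 1 and at 0.51 to 0.64 in the other postconfluent libraries. ELF3 went from 17.1 ± 1.47 to 161 ± 67.9 CPM (SD, n = 4), the nuclear receptor NR1I3 from 0.39 ± 0.179 to 10 ± 4.5 CPM and KLF5 from 62.2 ± 6.92 to 185 ± 41 CPM. HNF4A, a nuclear receptor of the enterocyte and hepatocyte lineages, was lower after confluence, at 201 ± 45.7 against 463 ± 46.5 CPM (log2 fold change -1.22, SE 0.16, edgeR adjusted p = 0.000172). Of 32 genes of junctions and adhesion, 13 rose and 7 fell. The claudin CLDN4 and the scaffold TJP3 rose by 2.19 (SE 0.19) and 1.51 (SE 0.15), and the pore-forming claudin CLDN2 fell by 1.85 (SE 0.19). Without subconfluent Z2flag replicate 1, 4 junction genes fell.

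The camera test placed digestive hydrolases (adjusted p = 0.000683), brush border structure (2.4e-05), lipid absorption (1.3e-10), xenobiotic metabolism (0.000372) and intestinal transcription factors (0.0314) above other genes, and not transporters (0.052) or junctions (0.195). None of these 5 calls was kept when camera estimated the correlation within each list: adjusted p = 0.444, 0.384, 0.384, 0.468 and 0.399 with an estimated correlation, in that order.

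Markers of other cell types gave a mixed picture. Of 11 colonocyte markers tested, 8 rose and 0 fell by edgeR's test (list median log2 fold change 4.03). CEACAM1 stood at 0.672 ± 0.238 and 22.7 ± 15.5 CPM (SD, n = 4) and HHLA2 at 0.696 ± 0.195 and 22.8 ± 15.5 CPM before and after confluence. In log2 CPM, the median colonocyte marker lay at 1.73 to 3.99 above the subconfluent mean in the postconfluent libraries. Some members had few counts, such as CEACAM5 with 10 subconfluent counts. Of 26 proteins secreted by hepatocytes, 23 rose and 0 fell: SERPINA1, the antitrypsin gene, went from 199 ± 77 to 2050 ± 534 CPM, AHSG, the fetuin gene, from 190 ± 79.8 to 2660 ± 718 CPM, and SERPINC1, the antithrombin gene, from 0.995 ± 0.602 to 24 ± 9.89 CPM. Of 9 goblet cell markers, 6 rose and 2 fell, and the trefoil factor TFF1 and the lectin ZG16 rose by 4.93 (SE 0.38) and 3.06 (SE 0.36). The 2 decreases became 1 without postconfluent Z1flag replicate 2, subconfluent Z1flag replicate 1, postconfluent Z2flag replicate 2 or either subconfluent Z2flag library, and 1 hepatocyte gene fell without postconfluent Z2flag replicate 2. Camera gave adjusted p = 0.000543 for colonocyte, 2.98e-09 for hepatocyte and 0.0316 for goblet lists, and adjusted p = 0.384 with an estimated correlation for each.

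Of 5 enteroendocrine markers tested 2 rose and 1 fell, of 6 Paneth cell markers 1 rose and 1 fell, and of 5 tuft cell markers 1 rose and 2 fell. In the enteroendocrine list the median log2 fold change was -0.70 while the mean, 0.16, and the camera test pointed up (adjusted p = 0.704). The calcium-binding protein SCGN rose from 2.10 ± 0.973 to 9.23 ± 2.37 CPM (SD, n = 4), the phospholipase PLA2G2A of Paneth cells from 0.168 ± 0.0573 to 1.98 ± 0.647 CPM, and IL17RB, a cytokine receptor, fell by 0.50 (SE 0.17) on the log2 scale, a call lost in 6 alternatives (adjusted p up to 0.176), among them those without replicate 2 of either Z1flag group and without replicate 1 of either Z2flag group. Of 6 fibroblast markers 2 rose and 3 fell, with COL1A1 up by 1.56 (SE 0.16), PDGFRA down from 84.7 ± 17.2 to 8.75 ± 3.68 CPM and COL3A1 down from 14.6 ± 6.33 to 2.10 ± 1.5 CPM. Of 9 leukocyte and endothelial markers 6 rose and 0 fell (7 rose when adjusted over the list alone), each at a low level, such as ITGAM at 0.744 ± 0.167 and 2.26 ± 0.594 CPM and PECAM1 at 6.26 ± 3.24 and 13 ± 6.32 CPM, which did not pass without subconfluent Z1flag replicate 1 or postconfluent Z2flag replicate 2 (adjusted p up to 0.105). PECAM1 changed by 1.91 in Z1flag (edgeR adjusted p = 0.0067) and by 0.13 in Z2flag cells (adjusted p = 0.825). This difference between lines did not pass the interaction test (adjusted p = 0.799). Camera gave adjusted p of 0.459 for Paneth, 0.719 for tuft, 0.437 for fibroblast and 0.0539 for leukocyte and endothelial markers.

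These short lists changed with single libraries. The 1 enteroendocrine decrease became 2 without postconfluent Z1flag replicate 1 and 0 without each of the others except subconfluent Z1flag replicate 1. Paneth cell increases numbered 3 without subconfluent Z1flag replicate 2, and 2 without either postconfluent Z1flag library or postconfluent Z2flag replicate 2. Tuft cell decreases numbered 0 without subconfluent Z1flag replicate 2 or replicate 1 of either Z2flag group and 1 without postconfluent Z1flag replicate 2, and its increase was lost without subconfluent Z1flag replicate 1 or subconfluent Z2flag replicate 2, leaving 0. The fibroblast median, -1.11 with all libraries, was 0.004 without subconfluent Z1flag replicate 2 and 0.023 without postconfluent Z2flag replicate 1.

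Of 51 genes of DNA replication, 47 fell and 0 rose by edgeR's test, with a median log2 fold change of -1.44 (adjusted p = 0.399 with an estimated correlation). BRCA1, a DNA repair gene, fell from 126 ± 9.07 to 35.3 ± 5.31 CPM (SD, n = 4), the transcription factor E2F8 from 80.4 ± 8.87 to 17.6 ± 4.09 CPM and the kinase CDC7, which fires replication origins, from 44.3 ± 2.25 to 12.2 ± 2.43 CPM. Of 47 genes of mitosis, 26 fell and 0 rose (median -0.67, adjusted p = 0.526 with an estimated correlation), among them HMMR, SGO1 and the kinesin CENPE (log2 fold changes -1.47, -1.35 and -1.49). Of 47 replication-dependent histone genes, 38 fell and 1 rose (median -1.07, adjusted p = 0.542 with an estimated correlation): H2AC4 and H3C12 fell by 2.23 (SE 0.23) and 1.96 (SE 0.27), and H4C9 rose by 1.01 (SE 0.32), a call lost in 4 alternatives (adjusted p up to 0.0897), leaving 0 increases without either subconfluent Z1flag library or subconfluent Z2flag replicate 2, against 2 without postconfluent Z1flag replicate 1. Histone genes of this class have near-identical copies, so single members are uncertain.

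The libraries differed in how far these lists fell. Relative to the subconfluent mean, the median mitosis gene lay at -1.32 on the log2 scale in postconfluent Z1flag replicate 1 and at -0.48 to -0.61 in the other 3 postconfluent libraries, and replication-dependent histones lay at -1.92 against -0.57 to -1.27. Without postconfluent Z1flag replicate 2, 43 mitosis genes fell, and without replicate 1, 4 of them rose. Without postconfluent Z2flag replicate 1, 22 histone genes fell. Camera called all 3 lists lower (adjusted p = 2.43e-16 for replication, 4.84e-06 for mitosis and 1.36e-06 for histones), and none of these calls was kept with an estimated correlation.

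Of 28 stem cell and Wnt pathway genes tested, 18 fell and 2 rose (median -1.17). Beside LGR5, the cell cycle kinase CDK6 fell from 527 ± 59 to 96.4 ± 20.3 CPM (SD, n = 4) and the chloride cotransporter SLC12A2 from 266 ± 79.1 to 33.9 ± 7.20 CPM, and the ephrin receptor EPHB3 rose by 2.32 (SE 0.27) on the log2 scale. Without postconfluent Z1flag replicate 1, 5 members rose, and without each of the others except postconfluent Z2flag replicate 2, 1 rose. Of 23 cyclin-dependent kinase inhibitors and quiescence genes, 12 rose and 4 fell: CDKN1A, the p21 inhibitor, went from 4.57 ± 0.471 to 42.2 ± 1.94 CPM, the MYC antagonist MXI1 from 7.34 ± 0.668 to 58.5 ± 7.83 CPM and the atypical cyclin CCNG2 from 8.17 ± 0.961 to 53.8 ± 9.35 CPM, and RBL1 fell by 0.91 (SE 0.13). Camera gave adjusted p of 1.45e-06 and 0.000242 for these lists, and adjusted p = 0.384 with an estimated correlation for both.

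Ribosome biogenesis was among the lists with the largest fall: 29 of 32 genes fell and 0 rose by edgeR's test (median -1.42). POLR1A and POLR1B, the large subunits of RNA polymerase I, fell from 222 ± 8.72 to 51.7 ± 7.18 CPM and from 130 ± 4.91 to 39.9 ± 2.92 CPM (SD, n = 4), and UTP20, a component of the small-subunit processome, fell from 207 ± 29.3 to 28.6 ± 7.23 CPM (camera adjusted p = 2.43e-16, and adjusted p = 0.384 with an estimated correlation). Of 33 nuclear-encoded genes of mitochondrial respiration, 10 fell and 0 rose, 9 when adjusted over the list alone, among them NDUFB3, ATP5PB and CYC1 (log2 fold changes -1.07, -0.81 and -0.99). Camera did not call this list (adjusted p = 0.0684), and without postconfluent Z1flag replicate 2, 16 of its genes fell and 2 rose. Of these genes, 3 rose without postconfluent Z1flag replicate 1, and without subconfluent Z1flag replicate 2 or postconfluent Z2flag replicate 2, 1 rose.

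Of 14 replication-independent histone variant genes, 3 rose and 4 fell (camera adjusted p = 0.719). The linker histone H1-10 rose from 36.6 ± 2.85 to 153 ± 64.1 CPM (SD, n = 4), and HIRA, a chaperone of histone H3.3, fell from 14.8 ± 0.768 to 5.84 ± 1.05 CPM. Leaving out postconfluent Z1flag replicate 1 gave 6 genes that rose, and the list median, 0.16, was -0.10 without postconfluent Z1flag replicate 2. The median member lay at -0.46 in postconfluent Z1flag replicate 1 and at 0.07 to 0.47 in the other postconfluent libraries.

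Genes of hypoxia and glycolysis rose in 18 of 29 cases and fell in 3. NDRG1 went from 3.61 ± 1.49 to 238 ± 34.6 CPM (SD, n = 4), the collagen hydroxylase P4HA1 from 101 ± 3.66 to 666 ± 111 CPM and the lactate transporter SLC16A3 from 1.66 ± 0.305 to 34.1 ± 14.6 CPM, while the oxygen sensor EGLN3 fell by 1.75 (SE 0.15) on the log2 scale. The median member lay at 0.02 in postconfluent Z1flag replicate 1 and at 1.11 to 1.40 in the other postconfluent libraries, and 8 genes fell without postconfluent Z1flag replicate 2. In the cholesterol synthesis list 11 of 24 genes rose and 4 fell: INSIG1 went from 111 ± 4.36 to 673 ± 222 CPM, MSMO1 and SREBF2 changed by 1.74 (SE 0.15) and 1.28 (SE 0.14), and PMVK fell by 0.71 (SE 0.18). The 4 decreases became 1 without subconfluent Z1flag replicate 2, postconfluent Z2flag replicate 1 or either subconfluent Z2flag library, and 2 without postconfluent Z1flag replicate 1. The median cholesterol gene lay at 0.08 in that library and at 0.43 to 0.87 in the other postconfluent libraries. Camera gave adjusted p of 3.14e-06 and 0.0128 for these lists, and adjusted p = 0.468 and 0.601 with an estimated correlation.

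Of 20 immediate early genes, which respond within minutes to growth factors or stress, 15 rose and 2 fell. JUNB went from 4.22 ± 0.355 to 41.4 ± 13.6 CPM (SD, n = 4), FOSB from 0.383 ± 0.202 to 6.46 ± 2.83 CPM and ZFP36 from 4.55 ± 0.725 to 35.2 ± 15.2 CPM, and the phosphatase DUSP2 fell by 1.57 (SE 0.27) on the log2 scale. Of 24 interferon response genes, 17 rose and 2 fell, with HLA-B at 7.45 ± 1.2 and 71.3 ± 23.9 CPM and IFIT2 at 0.383 ± 0.114 and 8.14 ± 3.38 CPM before and after confluence. Of 26 genes of the unfolded protein response, 11 rose and 3 fell: HERPUD1, DDIT3 and DNAJB9 rose by 1.64 (SE 0.19), 1.96 (SE 0.26) and 1.39 (SE 0.19), and CRELD2 fell by 1.42 (SE 0.20). Of 25 genes of mesenchymal transition and migration, 12 rose and 7 fell, among them the integrin ITGA3 (2.76, SE 0.15), CCN2 (2.81, SE 0.27) and the protease MMP14 (1.45, SE 0.17), with the laminin LAMA3 lower by -0.88 (SE 0.14).

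Camera called immediate early genes (adjusted p = 3.87e-06) and interferon response (8.17e-05) higher, with adjusted p = 0.384 with an estimated correlation for both, and did not call the unfolded protein response (0.0564) or the mesenchymal list (0.0564). The median immediate early gene lay at 1.27 above the subconfluent mean on the log2 scale in postconfluent Z1flag replicate 1 and at 1.88 to 2.46 in the others, and the median unfolded protein response gene at -0.15 against 0.50 to 0.58. Without that library 17 genes of the unfolded protein response rose, without postconfluent Z1flag replicate 2 5 fell, and without postconfluent Z2flag replicate 2 1 fell. The median mesenchymal gene lay at 1.22 in postconfluent Z2flag replicate 1 and at 0.07 to 0.41 in the other postconfluent libraries, and without subconfluent Z2flag replicate 2, 4 mesenchymal genes fell. Over all 30 lists camera made 19 calls and 0 with an estimated correlation, where the smallest adjusted p was 0.384 and 10097 single genes passed edgeR's test, and fry, which asks only whether a list's own genes move one way, made 22. The counts of members were the same when adjusted over the list alone, except where another count is given.

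**Figure D2:**
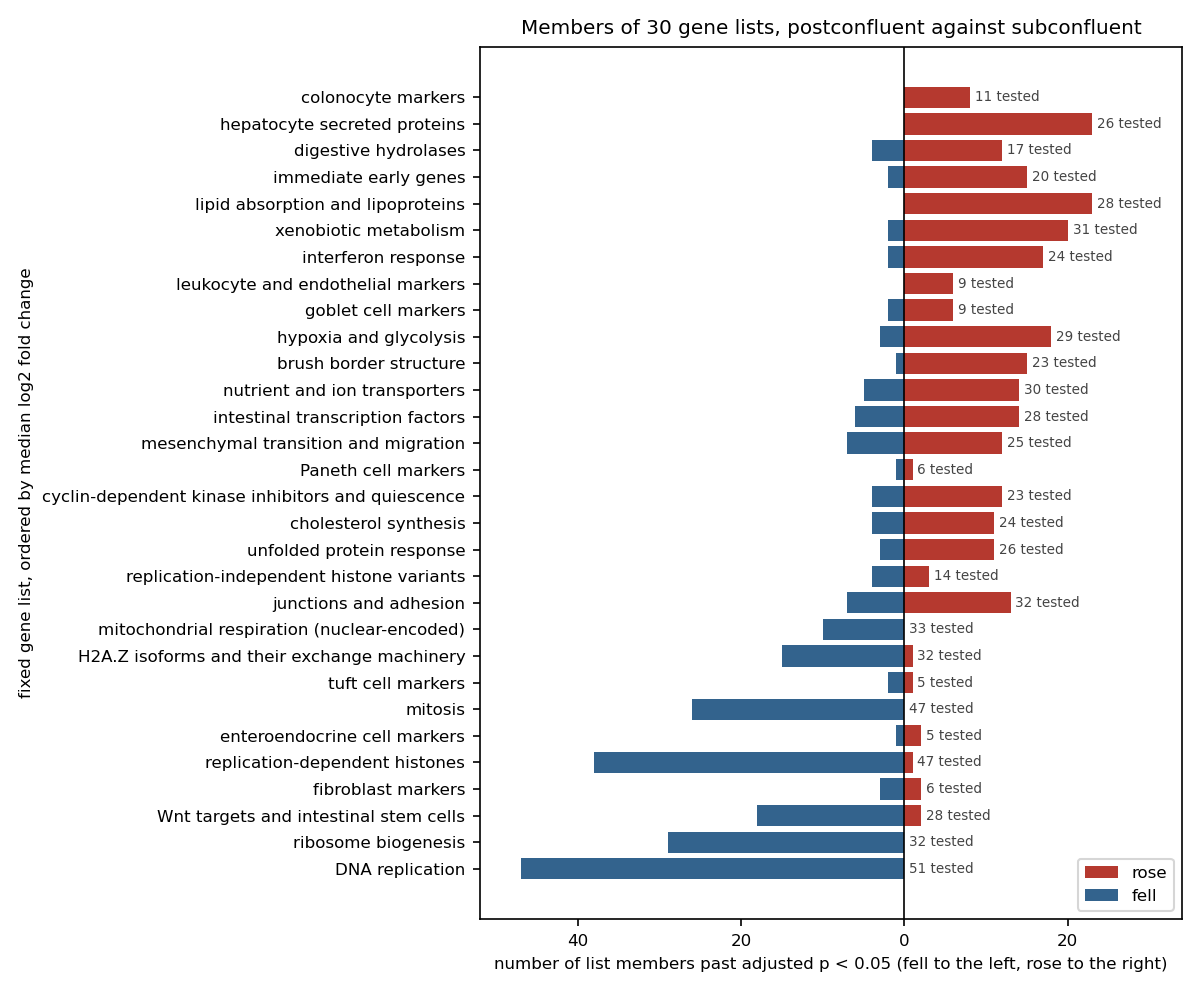
Number of members of each of 30 fixed gene lists that passed edgeR's test (adjusted p under 0.05) after confluence, with members that rose in red to the right and members that fell in blue to the left; the number tested stands beside each bar and lists are ordered by their median log2 fold change. Colonocyte markers (8 of 11 rose) and hepatocyte secreted proteins (23 of 26 rose) stand at the top and DNA replication (47 of 51 fell) at the bottom.

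The change was similar in both tagged lines. In Z1flag cells 7380 genes changed between states, 3890 higher and 3490 lower, and in Z2flag cells 6864, 3335 higher and 3529 lower. Both lines shared 2628 higher genes, where independent lists of these sizes would share 711, and 2551 lower genes, where 675 would be shared. In addition, 1 gene was higher in Z1flag and lower in Z2flag cells, and 0 had the opposite combination. The main fit shares its spread over the 4 groups, whose replicates differed unequally. Replicates correlated at r = 0.964 in postconfluent Z1flag and 0.995 in subconfluent Z2flag cells. With only the libraries compared, 5164 genes changed in Z1flag and 8589 in Z2flag cells, the reverse order. The numbers of changed genes therefore do not rank the lines. Across the 18240 genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson r = 0.852 and Spearman rho = 0.835, and these lines share no library. FXYD3 changed by 8.41 in Z1flag and 7.37 in Z2flag cells, NDRG1 by 6.48 and 5.67, LGR5 by -3.68 and -3.88, and UTP20 by -3.10 and -2.62.

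The number of calls within a line depended on single libraries, and it fell or rose with the library left out. Each such fit leaves a group with a single library. The largest falls were as follows. Without subconfluent Z1flag replicate 1 or 2, 3757 or 4358 genes changed in Z1flag cells. In Z2flag cells the count was 4177 without postconfluent replicate 1, and 3355 or 2894 without subconfluent replicate 1 or 2.

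**Figure D3:**
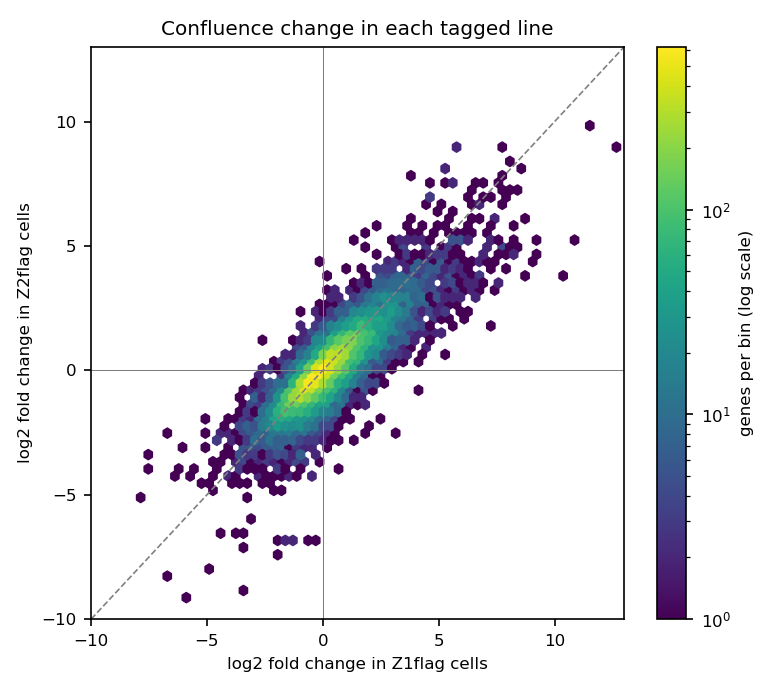
Log2 fold change after confluence in Z1flag cells (x axis) against Z2flag cells (y axis) for 18240 genes, as a hexagonal density with the number of genes per bin on a log colour scale and the line of equal change dashed. The genes spread around that line, with Pearson r = 0.852 across genes.

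No single gene passed the main test for a different confluence change in the 2 lines. This includes the 1 gene called higher in Z1flag and lower in Z2flag cells. The interaction test of edgeR called 0 genes (smallest adjusted p = 0.799), with 902 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0, while 41 were called with no filter on low counts. H2AZ1 and H2AZ2 differed between the lines in their confluence change by 0.17 (SE 0.37, adjusted p = 0.931) and 0.15 (SE 0.28, adjusted p = 0.917). The 3 genes with the smallest p, none of which passed, were LHPP, a phosphatase gene (-1.47, SE 0.44), NAMPT, an enzyme of NAD synthesis (1.19, SE 0.35), and TMEM86B, a lysoplasmalogenase gene (-1.79, SE 0.53), each with adjusted p = 0.799.

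At the level of lists, camera called 15 of 30. Hepatocyte secreted proteins, xenobiotic metabolism, digestive hydrolases, lipid absorption, brush border, transcription factor and tuft cell lists increased less or decreased more in Z2flag than in Z1flag cells, and mitosis, DNA replication, histone, mesenchymal, hypoxia, unfolded protein response, immediate early and ribosome biogenesis lists were shifted the other way. The largest median differences were -1.34 for hepatocyte secreted proteins (adjusted p = 1.29e-11) and -1.18 for tuft cell markers (adjusted p = 0.0408), both with adjusted p = 0.563 with an estimated correlation. None of the 15 passed with an estimated correlation (smallest adjusted p = 0.563) or with fry (smallest 0.728). Without postconfluent Z1flag replicate 1, 5 of the 15 passed camera in the same direction. In simulated data with these library sizes, the interaction test recovered 5.1% of genes changed 2-fold and 42.4% of genes changed 4-fold, and without postconfluent Z1flag replicate 2, which leaves replicate 1 alone in its group, it called 190 genes.

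Over both states edgeR called 0 genes between lines (smallest adjusted p = 0.319, with 465 at an unadjusted p under 0.05), limma voom 0 and DESeq2 2, with 16 called by edgeR when no filter on low counts was used. H2AZ1 was higher in Z2flag than in Z1flag cells by 0.23 (SE 0.19) and H2AZ2 by 0.11 (SE 0.14), both with adjusted p = 0.945 and both smaller than 2 SE, and the direction turned without the 2 libraries of highest no-feature share (-0.0143 and -0.0369) and, for H2AZ2, with that share as a covariate (-0.0091). Group means of H2AZ1 were 316 ± 34.7 and 349 ± 2.99 CPM (SD, n = 2) in subconfluent Z1flag and Z2flag cells, and 152 ± 63 and 189 ± 2.60 CPM after confluence. The 2 genes called by DESeq2, named after their values were seen, were THBS4, a matrix thrombospondin (log2 difference 2.87, SE 0.52, DESeq2 adjusted p = 0.000628, edgeR adjusted p = 0.319), and DSC3, a desmosomal cadherin (1.41, SE 0.29, DESeq2 adjusted p = 0.00787, edgeR adjusted p = 0.945), both higher in Z2flag cells.

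Within subconfluent cells edgeR called 0 genes between lines (195 at an unadjusted p under 0.05; limma voom and DESeq2 0), and within postconfluent cells 0 (1308 at an unadjusted p under 0.05; limma voom and DESeq2 0). With no filter on low counts the counts were 2 and 221, and a crossed replicate block, chosen after seeing the data, gave 46 in postconfluent cells. Without postconfluent Z1flag replicate 2, 2252 genes differed between postconfluent lines and 379 over both states. Camera called 14 lists between lines over both states, all higher in Z2flag cells and led by DNA replication (median difference 0.23, adjusted p = 9.2e-09) and mitochondrial respiration (0.20, adjusted p = 7.2e-08). None of them passed with an estimated correlation (adjusted p = 0.684 for both). Both of these lists were low in Z1flag replicates 1: relative to the subconfluent mean, the median DNA replication gene lay at -2.16 in postconfluent Z1flag replicate 1 and at -1.09 to -1.30 in the other postconfluent libraries, and the median respiration gene at -0.49 against -0.11 to -0.14. In subconfluent Z1flag replicate 1 these medians were -0.07 and -0.25, against -0.02 to 0.04 and 0.03 to 0.11 in the other subconfluent libraries. Within states, camera called 5 lists in opposite directions. Mitosis, replication-dependent histones and immediate early genes were placed lower in Z2flag cells when subconfluent (adjusted p = 0.0139, 7.47e-05 and 0.000771) and higher when postconfluent (9.73e-11, 0.0304 and 0.00574), and hepatocyte secreted proteins and xenobiotic metabolism higher when subconfluent (6.21e-15 and 4.39e-05) and lower when postconfluent (0.00105 and 0.000126). Z1flag replicates 1 stood apart here too. In subconfluent replicate 1 the median histone, immediate early, hepatocyte and xenobiotic genes lay at 0.28, 0.32, -0.97 and -0.51, against -0.14 to -0.03, -0.19 to -0.07, 0.15 to 0.67 and 0.10 to 0.33 in the other subconfluent libraries. In postconfluent replicate 1 the median hepatocyte gene lay at 2.95 against 1.54 to 2.58, and the median genes of the other 4 lists lay apart as given above. No list passed within a state with an estimated correlation, where the smallest was adjusted p = 0.441 with an estimated correlation in subconfluent and 0.654 in postconfluent cells. The edited populations are one per tag, so an effect of the tag and a difference between populations cannot be separated here. If the lines were grown in different experiments, that difference cannot be separated either.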

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

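The tests of other splits and of leaving out postconfluent replicates 1 were written before their results were seen, though it was already known that postconfluent Z1flag replicate 1 stood apart, and the test on immediate early genes was chosen after its result was seen. Of 252 groups of 4 libraries tested, 23 had a library far from the other 3, where chance gives about 1 in 20 groups.

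In log2 CPM, postconfluent Z1flag replicate 1 was low for H2AZ1 (6.75), H2AZ2 (5.42), HSPA6 (-0.02), SLC12A2 (4.54), LAMA3 (5.78) and DDIT3 (5.00). Postconfluent Z2flag replicate 1 was high for MYL7 (0.75), CLDN4 (8.99), CCN2 (5.10) and MMP14 (7.77) and low for SERPINA1 (10.29). Postconfluent Z1flag replicate 2 was low for SLC51A (3.42) and high for MYO1D (8.32). Subconfluent Z1flag replicate 1 was low for H2AZ1 (8.19), MYBPH (4.85), TFF1 (-1.72), AHSG (6.18) and NDUFB3 (5.23), and its no-feature share was 32.02%. Subconfluent Z1flag replicate 2 was low for ITGAM (-0.80) and high for TAP1 (1.07), and subconfluent Z2flag replicate 1 was high for PECAM1 (3.49) and MXI1 (3.07).

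Some classes of reads outside the gene counts differed between states. The ambiguous share was 7.20 ± 0.74% in postconfluent and 5.56 ± 0.13% in subconfluent libraries (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0381 over 8 measures), and the share aligned to more than 1 place 9.17 ± 1.01% and 6.73 ± 0.14% (exact permutation p = 0.0286, adjusted p = 0.0381), each higher in 4 of 4 libraries. The no-feature share, the largest class, did not differ (24.5 ± 4.77% and 26.0 ± 4.01%, exact permutation p = 0.457, adjusted p = 0.522).

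The confluence change of 15 lists differed between lines by camera, given as the median log2 difference, Z2flag minus Z1flag. It was negative for hepatocyte secreted proteins (-1.34), tuft cell markers (-1.18), xenobiotic metabolism (-1.03), digestive hydrolases (-0.81), lipid absorption (-0.65), brush border structure (-0.48) and intestinal transcription factors (-0.43). It was positive for immediate early genes (0.56), the mesenchymal list (0.53), mitosis (0.40), replication-dependent histones (0.29), DNA replication (0.28), hypoxia and glycolysis (0.25), the unfolded protein response (0.24) and ribosome biogenesis (0.23). With an estimated correlation the smallest adjusted p was 0.563.

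A candidate explanation of these list differences is the 1 library, postconfluent Z1flag replicate 1, that stands apart. Without it, 5 of the 15 lists passed in the same direction and 11 kept their direction, between the bounds set beforehand, so this library and a difference between the lines cannot be told apart. That most of the lists rest on postconfluent Z2flag replicate 1 alone was argued against, since 12 of 15 passed without it. Leaving out subconfluent Z1flag replicate 1 also left 12. A partial contribution of postconfluent Z2flag replicate 1 was not excluded, since lists shifted by another library could still pass. These counts use camera with the preset correlation. An effect of the tags stays open and untested, as each tag is in 1 population.

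Of 20 immediate early genes 15 rose after confluence (camera adjusted p = 3.87e-06, adjusted p = 0.384 with an estimated correlation), and a response to handling that differed between postconfluent libraries may contribute. Their median standard deviation among the 4 postconfluent libraries, 0.594, lay at percentile 99.85 of 10000 lists matched on expression and size of change (matched median 0.377). JUN stood at 35.1 CPM in postconfluent Z1flag replicate 1 and at 123 to 188 CPM in the other postconfluent libraries, while FOS stood at 251 and at 91.2 to 98.5 CPM. A response to confluence itself stays open, since the 15 genes rose in the mean over both lines.

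In an additive fit the real split of the 8 libraries by state gave 10018 genes and the highest other split 0. So 1 of 34 splits gave as many. The other splits were fitted without a state term, so the confluence change entered their spread and held their calls down. They therefore cannot exclude chance as the source of the confluence result. For the difference between lines the real split gave 0 genes by edgeR and the highest other 18. With 0 in the real split, 34 of 34 splits give as many whatever the data, so this count says nothing about chance.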

How the results depend on the processing

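The 2 libraries of highest no-feature share, that share as a covariate and the crossed replicate block were chosen after seeing the data, and the cause of the changes below was not tested except where stated. Genes higher in postconfluent cells stayed within 1.5 times 5076 in each alternative, 4044 to 6093 when a library was left out. Lower genes numbered 3965 to 5385 when a library was left out and 2394 with a fold change of at least 2, a stricter criterion by construction. Changed genes in Z1flag cells numbered 3757 to 8862 when a library was left out and 4865 without the 2 libraries of highest no-feature share, and in Z2flag cells 2894 to 9108 when a library was left out. The interaction gave 41 genes with no filter and 0 to 190 when a library was left out, where the lone sample of a group is assumed to vary like the other groups. Lines over both states gave 2 genes by DESeq2, 16 with no filter and 0 to 379 when a library was left out, subconfluent lines 2 with no filter, and postconfluent lines 221 with no filter, 46 with the crossed replicate block and 0 to 2252 when a library was left out. With only the libraries compared, 5164 genes changed in Z1flag and 8589 in Z2flag cells, which reversed the order of the main fit. Camera called 19 lists, 0 with an estimated correlation, 22 by fry and 23 with a replicate block. The correlation between lines was 0.671 to 0.839 when a library was left out. The difference between lines of H2AZ1 was -0.0143 and of H2AZ2 -0.0369 without the 2 libraries of highest no-feature share, and of H2AZ2 -0.0091 with that share as a covariate. For the confluence change of 116 named genes, 2397 of 2428 values kept direction and call, 31 kept direction only, and none reversed. Most of these 116 genes were named for their large change or small adjusted p in the same data. How they held up therefore does not measure how the other calls would. Depth limits genes with few counts, such as HSPA6 with 2 subconfluent counts.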

Other observations

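The gene families here were defined after the data were seen, and all tests on ribosomal protein genes were chosen after the result was seen. Of 79 cytosolic ribosomal protein genes, 76 rose after confluence and 1 fell, with a median log2 fold change of 1.25 (camera adjusted p = 1.69e-30, adjusted p = 0.518 with an estimated correlation). RPL31 changed by 1.76 (SE 0.14) and RPL13A by 1.75 (SE 0.14). Mitochondrial ribosomal proteins went the other way: 53 of 77 fell and 1 rose (median -0.56, camera adjusted p = 1.47e-07, adjusted p = 0.559 with an estimated correlation), among them MRPL15 (-1.75). Of 18 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 13 fell and 1 rose (median -0.79, camera adjusted p = 0.000748, adjusted p = 0.559 with an estimated correlation), with WARS1 at -1.88 and QARS1 at 0.84. The median mitochondrial ribosomal gene lay at -0.91 in postconfluent Z1flag replicate 1 and at -0.47 to -0.57 in the other postconfluent libraries. For the synthetases these values were -1.25 and -0.45 to -0.84. Of 25 collagens, 15 rose and 6 fell (median 1.17, camera adjusted p = 0.00154, adjusted p = 0.518 with an estimated correlation), with COL6A1 at 3.27 and COL6A2 at 3.79.

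Other families showed no common direction. Of 15 heat shock protein and cochaperone genes 6 rose and 4 fell (median 0.09, against 0.27 with upper-quartile scaling and 0.37 without the 2 libraries of highest no-feature share), their median member lay at -0.79 in postconfluent Z1flag replicate 1 and at -0.01 to 0.67 in the other postconfluent libraries, and HSPA1A and HSPA1B, near-identical copies, changed by 2.47 (SE 0.36) and 2.72 (SE 0.42). Of 242 solute carriers 92 rose and 63 fell (median 0.15, against 0.34 with upper-quartile scaling). Of 10 keratins 3 rose and 4 fell, and the median, -0.17, was 0.02 with upper-quartile scaling. Of 407 ZNF genes 85 rose and 81 fell, and the median, -0.01, was 0.02 with RLE and 0.18 with upper-quartile scaling. The 1 metallothionein tested, MT1F, changed by 1.48 (SE 0.27). By gene type, 346 lincRNA genes rose and 146 fell of 997 tested, 336 antisense genes rose and 159 fell of 1106, and 3606 protein-coding genes rose and 4273 fell of 13184. Counts of antisense genes, which the lncRNA share includes, are uncertain to the extent that the counting ignored strand. The share of gene counts from lncRNA genes was 3.68 ± 0.63% after and 1.52 ± 0.09% before confluence (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0381).

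The rise of ribosomal protein mRNAs was weighed against technical explanations. For length, GC content or expression level of these genes, their median lay at percentile 100 of 10000 lists matched on these (matched median -0.02, from -0.27 to 0.18). Length and GC content were those of each gene's longest annotated transcript, and the closeness of the matches was not measured. These values therefore argue against the 3 traits only as far as the matching reached. The multi-mapped share was 2.45 points higher after confluence. A share over all genes does not show how reads of ribosomal protein genes were assigned, so reads moved from that class into gene counts stay open. Pseudogenes held 1.11 ± 0.13% of gene counts after and 1.47 ± 0.26% before confluence (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0381). The choice among 4 scalings was argued against, since the lowest ribosomal protein median was 1.22. These scalings moved the median of all genes only between -0.036 and 0.179. A change of these mRNAs with confluence is a hypothesis consistent with these values, found and tested on the same data, and RNA integrity and library batch were not tested.

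Groups did not overlap for 4577 genes higher and 4766 lower after confluence, where chance gives 1.43% of genes each. Olfactory receptor genes, a class with little expression outside sensory tissue, stood at 14.1 CPM in postconfluent Z1flag replicate 1 and 5.94 to 9.53 in the other libraries.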
